A study of Mus musculus with 3 samples.

How the data were processed

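RNA was measured in 3 libraries of cultured MSCs from fat pads of adult C57BL/6 mice. Per the labels' protocols, the miRNeasy kit was used to purify RNA and the TruSeq V2 kit to make libraries from total RNA. The authors deposited a single table of RPKM values, in which each gene has an Ensembl identifier, a symbol, a biotype and a value per library. The genome build is mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the reads that the library size counts are not given in the sources used here. No read counts were used here. Replicate numbers follow the sample titles, and nothing in the labels says whether the 3 libraries came from separate mice or cultures, so the SDs may be technical.

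The table held 43346 genes, of which 22032 were protein-coding. 42462 identifiers matched GENCODE M21, which is also on mm10 and supplied coordinates and exon lengths; the other 884 have no length here. The RPKM as deposited was the main scale. Levels were tested as log2(RPKM + 1), which understates differences between low genes. The depth was inferred from low values, since a gene with 1 read has an RPKM fixed by its length and the library total. The totals came to 28819400, 32997000 and 32033200 reads for libraries 1, 2 and 3. With these, 81.0% of 3133 genes below 10 reads came out within 0.05 of a whole number in all 3 libraries. These totals are an inference and were used for counting precision and for the share of reads at Gm23935. Intervals and floors cover counting error only.

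The design has a single group, so no test between conditions was made. Before the data were examined, 35 gene lists with 383 members, 7 contrasts between lists, the detection threshold and the rule for named genes were fixed. 382 members were found, Adgre1 under its older symbol Emr1 by identifier; Hbb-b1 was not matched. The named genes were the 20 of highest mean outside mitochondrial, ribosomal protein and small structural RNA genes, up to 4 highest and the lowest member of each list (all members of the MSC surface, haematopoietic, interstitial matrix, progenitor, adipocyte and sex chromosome lists), the 15 of largest SD, and for each library the 5 farthest above and below both others; the text gives a selection of them, and some are not reported here. Genes named outside this rule, in the closing part only, were chosen after their values were seen.

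Contrasts between lists used a two-sided permutation test of list membership on the mean log2(RPKM + 1) over libraries, exact where all divisions could be enumerated and otherwise with 100000 resamples, adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each list's median was placed among 10000 random lists of the same size, and its median SD among as many lists matched on expression (each member replaced by a draw from the 100 nearest genes). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and BLAST 2.17.0 were used.

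The procedures were tested on simulated data for 42462 genes in 3 libraries. Genes changed 2.5-fold in a single library were recovered as apart in 78.0% and genes changed 4-fold in 99.0% of cases, with 40 unchanged genes called among 12876. The simulation gave every gene the same variation beyond counting noise, a coefficient of variation of 0.05. These rates therefore need not hold for structural RNA genes, many of which varied more between the libraries. With no difference between lists the permutation test gave p below 0.05 in 3.50% of 200 draws. Random gene lists lay above the 95th percentile of level in 4.50% of 200 draws, and above the 95th percentile of matched spread in 7% of 100 draws. The genes of these draws were picked at random, so the rates check the procedures and do not cover lists of genes that vary together. On the inferred reads of protein-coding genes with a mean of 10 to 100 reads, the median chi-square between a pair of libraries was 2.44 to 2.79 times that of counting noise, and 4.56 to 6.00 times for genes of 1000 reads or more. With the reads halved, as for mates counted singly, the ratios were 1.22 to 1.39 and 2.28 to 3.00. The 3 libraries were counted as replicates because the labels list them as separate samples. The alternatives were other pseudocounts, filters, scalings, list centres and thresholds and leaving out each library; random lists and counts restricted to protein-coding genes were added after seeing the data. Sequence copies of structural RNA and mitochondrial genes were found with BLAST at 90% identity or more.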

Results

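Gene expression was profiled by RNA sequencing in mesenchymal stem cells (MSCs, adherent stromal cells that can be grown out of many tissues) isolated from the fat pads of adult C57BL/6 mice and cultured before RNA extraction. The study concerns transplanting such cells to limit narrowing of the vein in arteriovenous fistulas made for haemodialysis, and these libraries describe the cells themselves. All 3 libraries belong to a single group, so no comparison between conditions was possible, and the comparisons made were between gene groups within the cells and between the 3 libraries. The table gave a value for 43346 genes. A gene at an RPKM (reads scaled to the length of the gene model and to the size of the library) of 1 or more in all 3 libraries was called detected, which held for 12286 genes, 10447 of them protein-coding. The step size of the low values implied scaling totals of 28819400, 32997000 and 32033200 reads for libraries 1, 2 and 3. At that depth 3 reads in a gene model of 1 kb correspond to an RPKM of 0.104, 0.0909 and 0.0937 in libraries 1, 2 and 3, which is the level below which a 1 kb transcript could not be told from absent, counting error only. Values below are the mean RPKM ± SD over the 3 libraries (n = 3) unless another unit is named.

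Genes for contractile and matrix proteins were among the most abundant messenger RNAs of the cells, ribosomal protein genes being left out of the ranking. Acta2, which encodes smooth muscle alpha-actin, had the highest level of any protein-coding gene at 2328 ± 58.7 (chromosome 19, 34241090 to 34255590 of the mouse mm10 assembly). It was followed by the cytoskeletal actin Actb at 2225 ± 15, the matricellular gene Thbs1 at 1872 ± 47.2 (chromosome 2, 118111876 to 118127133) and the type I collagen gene Col1a1 at 1754 ± 71.0 (chromosome 11, 94936224 to 94953042). Sparc, which encodes osteonectin, stood at 1307 ± 59.6. Next came the actin-binding gene Tagln at 1164 ± 32.2 and the fibronectin gene Fn1 at 1162 ± 21.2. The calcium-binding gene S100a6 stood at 1136 ± 59.6 and the ferritin heavy chain gene Fth1 at 1047 ± 68.8. The acute-phase gene Saa3 had 827 ± 37.5, the galectin gene Lgals1 820.3 ± 19.2, the myosin light chain gene Myl6 807 ± 8.35, the type IV collagen gene Col4a1 706 ± 17.2 and the tropomyosin gene Tpm4 625 ± 14.3. Among noncoding transcripts outside the small structural RNAs, Malat1 stood at 3134 ± 196. The adjacent loci Gm26917 and Yam1 on chromosome 17 had values of 5169 ± 1013 and 19669.5 ± 6231. A ribosomal RNA precursor sequence was not used here, so whether the reads at both loci came from them was not tested.

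The surface marker definition of MSCs has a positive and a negative part, and genes for both were examined. Only their RNA was measured, not protein at the cell surface. 10 of the 10 MSC surface markers were detected. The integrin gene Itgb1 was the highest at 329 ± 13, followed by the adhesion gene Vcam1 at 56.6 ± 2.36 and the growth factor receptor genes Pdgfrb at 52.5 ± 0.383 and Pdgfra at 39.1 ± 1.76. The hyaluronan receptor gene Cd44 had 40.6 ± 0.683, Thy1, which encodes CD90, 35.9 ± 0.0776, and Eng, which encodes CD105, 13.9 ± 0.573. Ly6a, which encodes Sca-1, stood at 5.86 ± 0.462 and Alcam at 3.18 ± 0.111. Nt5e, which encodes CD73, was the lowest of the list at 1.15 ± 0.0916. Of the haematopoietic lineage markers 1 of 10, Cd14, was detected, at 2.63 ± 0.0764. Itgam had 1.08 ± 0.257, H2-Ab1 0.952 ± 0.181, Cd34 0.474 ± 0.122, the pan-leukocyte gene Ptprc 0.136 ± 0.00706 and Kit 0.0889 ± 0.0269. H2-Aa, Cd79a and Ly6g stayed at or below 0.0416 in each library. The mean log2(RPKM + 1) of the surface markers exceeded that of the haematopoietic markers by 4.09 ± 0.02 (SD over libraries, n = 3), with adjusted p = 0.000152, unadjusted p = 2.17e-05 in a two-sided exact permutation test of list membership. This and the other tests between lists treat genes as the units, which are not independent replicates, and were adjusted by the Benjamini-Hochberg method over 7 contrasts.

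**Figure D1:**
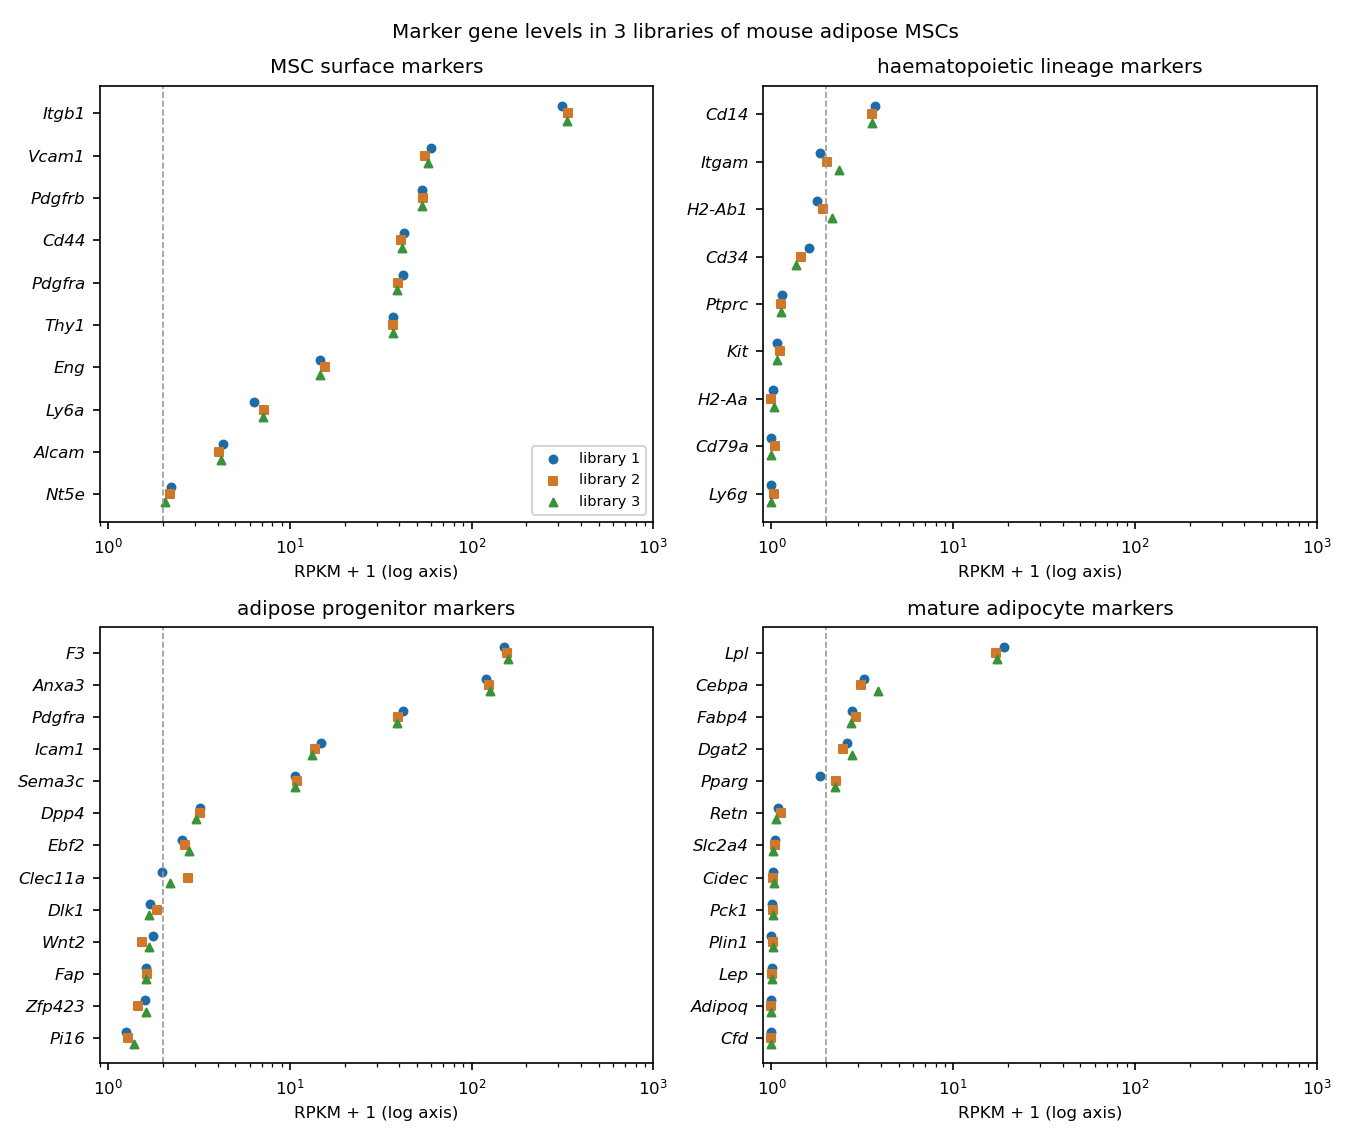
Level of members of 4 marker lists in each of the 3 libraries, as RPKM + 1 on a logarithmic axis, with symbols for libraries and a dashed line at an RPKM of 1. All 10 MSC surface markers lie to its right in every library, from Nt5e near 1.15 to Itgb1 near 329, while Cd14 alone of the haematopoietic markers shown does so in all 3.

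Genes of the adipose lineage were compared to ask whether the cultures resembled progenitors or fat cells. 7 of the 13 adipose progenitor markers were detected, led by the tissue factor gene F3 at 154 ± 3.29, Anxa3 at 123 ± 2.88, Pdgfra at 39.1 ± 1.76, Icam1 at 13 ± 0.763 and Sema3c at 9.74 ± 0.139. Dpp4 stood at 2.16 ± 0.0906, Ebf2 at 1.66 ± 0.127 and Clec11a at 1.31 ± 0.400. Dlk1, Wnt2, Fap, Zfp423 and Pi16 ranged from 0.309 to 0.745. 4 of the 13 mature adipocyte markers were detected, namely the lipoprotein lipase gene Lpl at 16.9 ± 1.02, Cebpa at 2.39 ± 0.395, the fatty acid binding gene Fabp4 at 1.82 ± 0.0797 and Dgat2 at 1.62 ± 0.140. Pparg, the central transcription factor of fat cell formation, stood at 1.11 ± 0.236. The lipid droplet genes Plin1 and Cidec had 0.0107 ± 0.00928 and 0.0229 ± 0.00939, the leptin gene Lep had 0.00957 ± 0.000691, and Retn, Slc2a4 and Pck1 had 0.0939 ± 0.0379, 0.0338 ± 0.0139 and 0.0153 ± 0.00453. The adiponectin gene Adipoq and the adipsin gene Cfd were listed at 0 in all 3 libraries. The progenitor list exceeded the adipocyte list by 1.86 ± 0.02 on the log2(RPKM + 1) scale (adjusted p = 0.0375, unadjusted p = 0.0214, two-sided permutation test). In the same permutation test the call was lost when members below an RPKM of 0.1 in every library were left out (difference 0.97, adjusted p = 0.398) and after rescaling to TPM (each library scaled to the same sum; difference 1.35, adjusted p = 0.0558), the adjusted p ranging from 0.0123 to 0.398 over the alternatives.

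Markers of other differentiated lineages were mostly near the floor. 2 of the 9 osteogenic genes were detected, Spp1, which encodes osteopontin, at 70.7 ± 3.31 and the bone transcription factor Runx2 at 2.68 ± 0.0608, whereas Alpl stood at 0.622 ± 0.0482 and Sp7 at 0.0630 ± 0.0284, and Sost was listed at 0. 1 of the 9 chondrogenic genes, the transcription factor Sox9 at 3.88 ± 0.386, was detected, while Col10a1 had 0.149 ± 0.0394 and Hapln1 was listed at 0. The difference between the osteogenic and chondrogenic lists, 0.67 ± 0.03 on the log2(RPKM + 1) scale, did not pass the exact permutation test (two-sided, adjusted p = 0.470, unadjusted p = 0.470), and with list medians in place of means it became -0.041. Of 8 skeletal muscle genes 1, the skeletal actin gene Acta1 at 28.6 ± 0.567, was detected. Tnnt3 stood at 0.626 ± 0.204 and Ckm was listed at 0. Of 7 pluripotency factors 2 were detected, Klf4 at 23.0 ± 0.974 and Myc at 14.6 ± 0.215, both of which are also expressed widely in somatic cells. Nanog stood at 0.133 ± 0.0265 and Sox2 at 0.0220 ± 0.00849.

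Markers of vascular and other cell types that a fat pad culture could hold were then examined. 10 of the 12 mural and myofibroblast genes were detected. Beside Acta2 and Tagln, the tropomyosin genes Tpm2 and Tpm1 had 621 ± 23.4 and 419 ± 8.52, and the pericyte gene Rgs5 had 0.0688 ± 0.0336. 1 of the 10 endothelial genes was detected, the VEGF receptor gene Kdr at 1.28 ± 0.0891. Cdh5 had 0.657 ± 0.0480, Tek 0.317 ± 0.0578 and Egfl7 0.305 ± 0.0921, and Cldn5 was listed at 0. The mural and myofibroblast list exceeded the endothelial list by 6.08 ± 0.06 (adjusted p = 0.000612, unadjusted p = 0.000175, two-sided exact permutation test). All 9 mesothelial genes were detected, among them Upk1b at 70.1 ± 5.23, Upk3b at 43.7 ± 3.30, the keratin gene Krt18 at 29.0 ± 0.635 and Lrrn4 at 22.9 ± 0.357, with Krt19 the lowest at 4.08 ± 0.10. 7 of the 12 macrophage genes were detected, led by the lysozyme gene Lyz2 at 26.2 ± 1.51, the complement gene C1qb at 4.32 ± 0.0518, Cd68 at 3.42 ± 0.469 and C1qa at 3.05 ± 0.230, while Cd163 stood at or below 0.0417 in each library. 3 of the 8 glial and neural genes were detected, Tubb3 at 39.6 ± 0.773, Nes at 23.5 ± 0.439 and Mbp at 3.04 ± 0.222, with Sox10 the lowest at 0.0158 ± 0.0175. No member of the lymphocyte, epithelial or erythroid lists was detected. The highest of these were Cd79b at 0.0299 ± 0.0331, Krt14 at 1.09 ± 0.194 and Alas2 at 0.0996 ± 0.0471, respectively.

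The interstitial matrix list had the highest median of the lists examined. All 18 interstitial matrix genes were detected, with a median log2(RPKM + 1) of 8.09 ± 0.03. After Thbs1, Col1a1, Sparc and Fn1 came the collagen genes Col1a2 at 528 ± 10.1, Col5a2 at 467 ± 5.94, Col3a1 at 418 ± 6.68 and Col5a1 at 267 ± 7.13 and the crosslinking enzyme gene Lox at 441 ± 11.3. Bgn had 278 ± 7.36, Fbn1 201 ± 5.74, Dcn 85.4 ± 4.01 and Col6a1 60.4 ± 1.85. Postn, Col6a3 and Col6a2 had 30.9 ± 0.526, 25.4 ± 0.335 and 18.8 ± 1.02. The elastin gene Eln at 4.62 ± 0.371 and Lum at 2.03 ± 0.212 were the lowest. All 10 basement membrane genes were detected, Col4a1 being followed by Col4a2 at 437 ± 4.59, the nidogen gene Nid1 at 173 ± 2.10 and the perlecan gene Hspg2 at 134 ± 5.04, with Lama4 the lowest at 9.57 ± 0.226. The difference between both matrix lists, 0.94 ± 0.02, did not pass the test (adjusted p = 0.414, unadjusted p = 0.355, two-sided permutation test). 12 of the 13 matrix protease genes were detected, led by the membrane-type protease gene Mmp14 at 250.2 ± 7.62, Adamts5 at 76.2 ± 2.40, Adamts1 at 59.9 ± 2.26 and the gelatinase gene Mmp2 at 56.2 ± 0.521, whereas Mmp9 stood at 0.104 ± 0.0343. 7 of the 8 inhibitor genes were detected, among them Timp1 at 347 ± 18.1, Timp3 at 208 ± 3.32 and Timp2 at 201 ± 7.77, while Timp4 was listed at 0. Proteases lay below inhibitors by a difference of -1.52 ± 0.04 on the log2(RPKM + 1) scale, which did not pass the exact permutation test (two-sided, adjusted p = 0.346, unadjusted p = 0.247). All 8 genes of the TGF-beta response list were detected. Among them Ctgf had 427 ± 7.52, Cyr61 324 ± 6.86 and Ltbp2 167 ± 3.68, and Tgfbi was the lowest at 1.91 ± 0.0952.

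Genes for secreted and immune factors were unevenly represented. 15 of the 17 angiogenic and growth factor genes were detected, led by Vegfa at 65.5 ± 1.97, Tgfb3 at 40.5 ± 0.612, and Fgf2 at 34.4 ± 1.09, with Angpt1 the lowest at 0.158 ± 0.0164. 11 of the 17 cytokine and chemokine genes were detected, led by the macrophage growth factor gene Csf1 at 266 ± 9.89, the monocyte chemoattractant genes Ccl2 and Ccl7 at 101 ± 2.57 and 73.5 ± 1.98, and Cxcl1 at 27.8 ± 0.154, while Csf2 stood at or below 0.0390 in each library. 7 of the 12 immune modulator genes were detected. After Lgals1, the haem oxygenase gene Hmox1 had 55.8 ± 2.98, Lgals9 38.4 ± 0.986 and the prostaglandin synthase gene Ptgs2 30.9 ± 1.41, and the nitric oxide synthase gene Nos2 had 0.0242 ± 0.0356. 11 of the 12 hypoxia and glycolysis genes were detected, with Aldoa at 203 ± 1.04, Ldha at 152 ± 2.05, Hif1a at 64.0 ± 0.139 and Pgk1 at 53.6 ± 0.632, and the carbonic anhydrase gene Car9 the lowest at 0.375 ± 0.134.

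Genes of the cell cycle were detected together with cell cycle inhibitors. All 16 proliferation genes were detected, from Mki67 at 27.1 ± 0.387, Top2a at 18.5 ± 0.617, Mcm6 at 13.1 ± 0.322 and Mcm3 at 12.7 ± 0.419 to Bub1 at 3.29 ± 0.122. 7 of the 8 genes of the senescence list were detected, Igfbp3 at 117 ± 5.37, the inhibitor gene Cdkn1a at 64.7 ± 1.87, Lmnb1 at 31.8 ± 1.08 and Cdkn2b at 19.8 ± 2.27, with Igfbp5 the lowest at 0.514 ± 0.0771. Lmnb1 is known to decline in senescent cells, unlike the other members. All 11 immediate early and heat shock genes were detected, among them Junb at 34.6 ± 0.924, Dusp1 at 28.9 ± 0.716, Ier3 at 25.1 ± 1.49 and Jun at 21.6 ± 1.91, with Atf3 at 1.30 ± 0.247. All 10 housekeeping genes were detected, from Actb, Eef1a1 at 934 ± 16.5, Rplp0 at 499 ± 17.6 and B2m at 215 ± 9.82 to Tbp at 1.09 ± 0.0864. The 8 mitochondrially encoded genes of the fixed list, mt-Nd1, mt-Co1 and mt-Cytb among them, were each listed at 0 in all 3 libraries, as was every other gene of the mitochondrial chromosome.

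The labels do not name the fat depot, so genes reported to differ between depots were compared. All 4 visceral depot genes were detected, Gata6 at 21.8 ± 0.709, Bnc1 at 13.4 ± 0.646, Wt1 at 12.6 ± 0.953 and Tcf21 at 11.4 ± 0.438. 3 of the 5 subcutaneous depot genes were detected, Sfrp2 at 8.30 ± 0.552, En1 at 4.58 ± 0.0840 and Hoxc10 at 1.70 ± 0.345, while Tbx15 had 0.908 ± 0.0340 and Shox2 0.668 ± 0.140. The visceral list exceeded the subcutaneous list by 2.18 ± 0.07 (adjusted p = 0.0370, unadjusted p = 0.0159, two-sided exact permutation test). With list medians in place of means the difference was 2.38 and the adjusted exact p was 0.10, within a range of 0.0278 to 0.10 over the alternatives. Wt1 is also on the mesothelial list, whose members were all detected. Which cells of the culture expressed the visceral depot genes was not tested. 24 of the 39 HOX cluster genes, which record position along the body axis, were detected, led by Hoxc8 at 18.6 ± 0.833, Hoxc6 at 11.3 ± 0.345, Hoxa5 at 7.69 ± 0.702 and Hoxb7 at 7.39 ± 0.731, and Hoxd13 was listed at 0. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 16.7 ± 0.484, 6.98 ± 0.135, 2.38 ± 0.101 and 1.79 ± 0.0354, and Xist was listed at 0 in all 3 libraries.

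**Figure D2:**
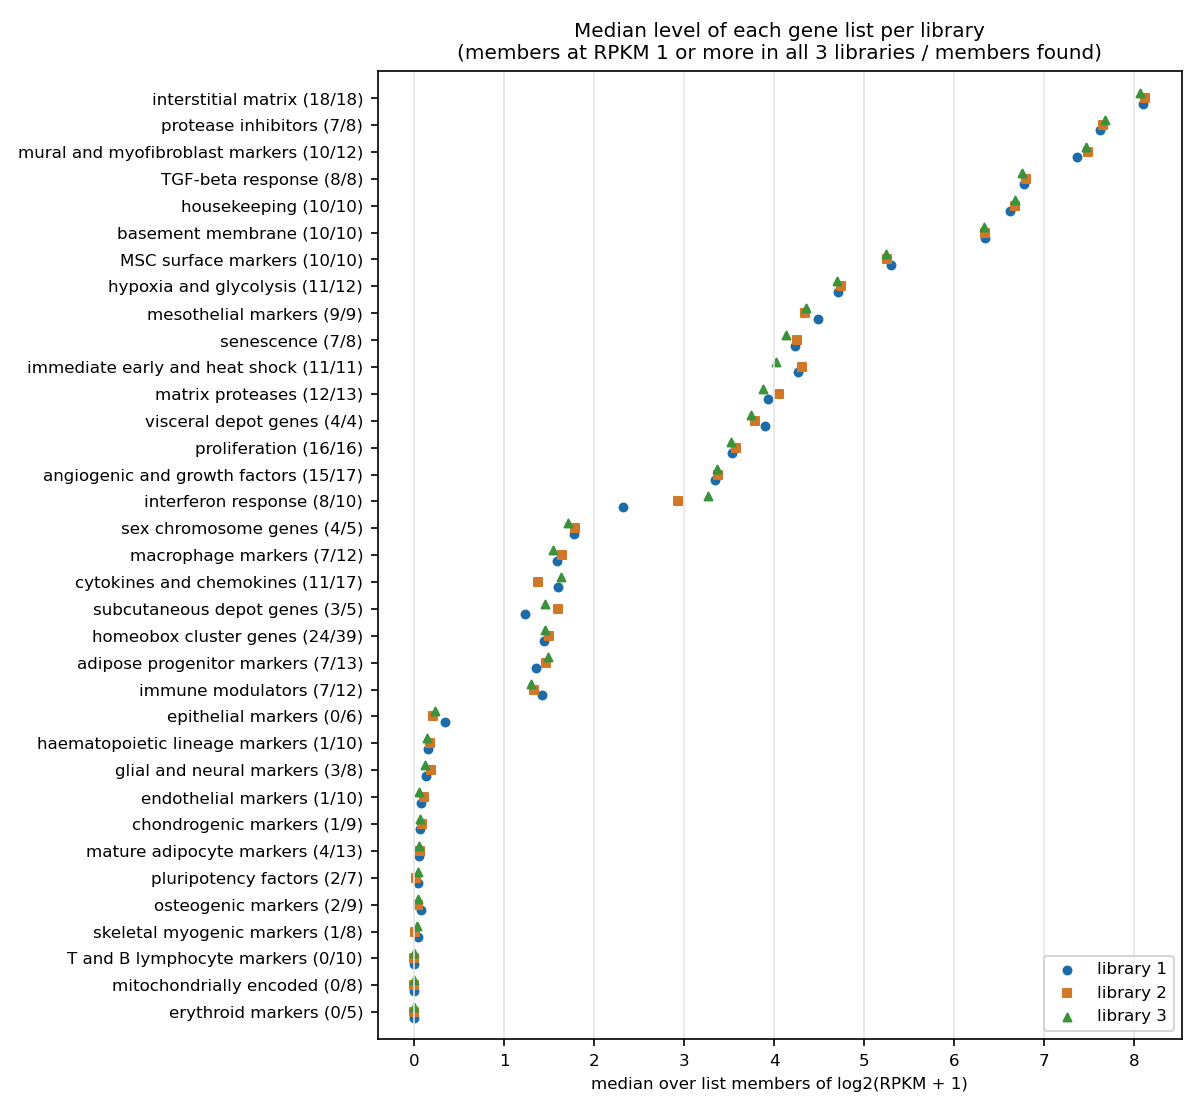
Median level of each of the 35 gene lists in each library, as the median over members of log2(RPKM + 1), where symbols are libraries and the fractions give detected members over members found. Interstitial matrix is the highest at 8.09, and the 3 libraries lie close together in most lists, interferon response being the most separated at 2.31, 2.93 and 3.26.

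Measured against random lists of the same size drawn from all genes, 19 of the 35 lists had a median above the 97.5th percentile, and 15 did so against protein-coding genes alone. The MSC surface list stood at percentile 100 among lists drawn from all genes and 100 among lists of protein-coding genes. The haematopoietic list stood at 60.7 among lists drawn from all genes and 19.5 among lists of protein-coding genes. The macrophage list stood at 97.54 among lists drawn from all genes, at the limit, and at 73.5 among lists of protein-coding genes. Without library 2 it stood at 97.31 among lists drawn from all genes, below the limit, and 18 lists were then above it. The mesothelial list stood at 99.99 among lists drawn from all genes and 99.98 among lists of protein-coding genes, the adipose progenitor list at 97.0 among lists drawn from all genes and 67.4 among lists of protein-coding genes, and the mature adipocyte list at 44.1 among lists drawn from all genes and 10.3 among lists of protein-coding genes.

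The 3 libraries differed little in their messenger RNAs, with the interferon response list as the clearest exception among the lists compared. 8 of the 10 interferon response genes were detected. Library 1 had the lowest and library 3 the highest level in 7 of the 8 interferon genes with a mean RPKM of 1 or more. The levels in libraries 1, 2 and 3 were 3.54, 7.07 and 10.0 for the interferon-induced gene Ifit3 and 14.8, 19.5 and 27.5 for the ubiquitin-like gene Isg15. They were 8.51, 8.91 and 11.9 for Oasl2 and 27.9, 26.4 and 34.6 for Bst2, the highest of the list, in which library 2 was the lowest. Mx1, the lowest, had 0.0667, 0.166 and 0.180. The median SD between libraries of the 8 genes was 0.31 on the log2(RPKM + 1) scale, above the 0.10 that marks the 97.5th percentile of 10000 random lists of protein-coding genes matched on expression. Without libraries 1, 2 and 3 in turn it was 0.27, 0.42 and 0.20, each above the 97.5th percentile of lists matched over all biotypes. Of the other 24 lists with at least 3 such members, the immediate early and heat shock list also lay above that percentile among protein-coding lists, with a median SD of 0.0934 against a limit of 0.0866, but not among lists of all biotypes. The MSC surface list had a median SD of 0.0562, the macrophage list 0.0831 and the basement membrane list 0.0267. With a single group of 3 libraries no p-value was given for a difference between libraries.

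**Figure D3:**
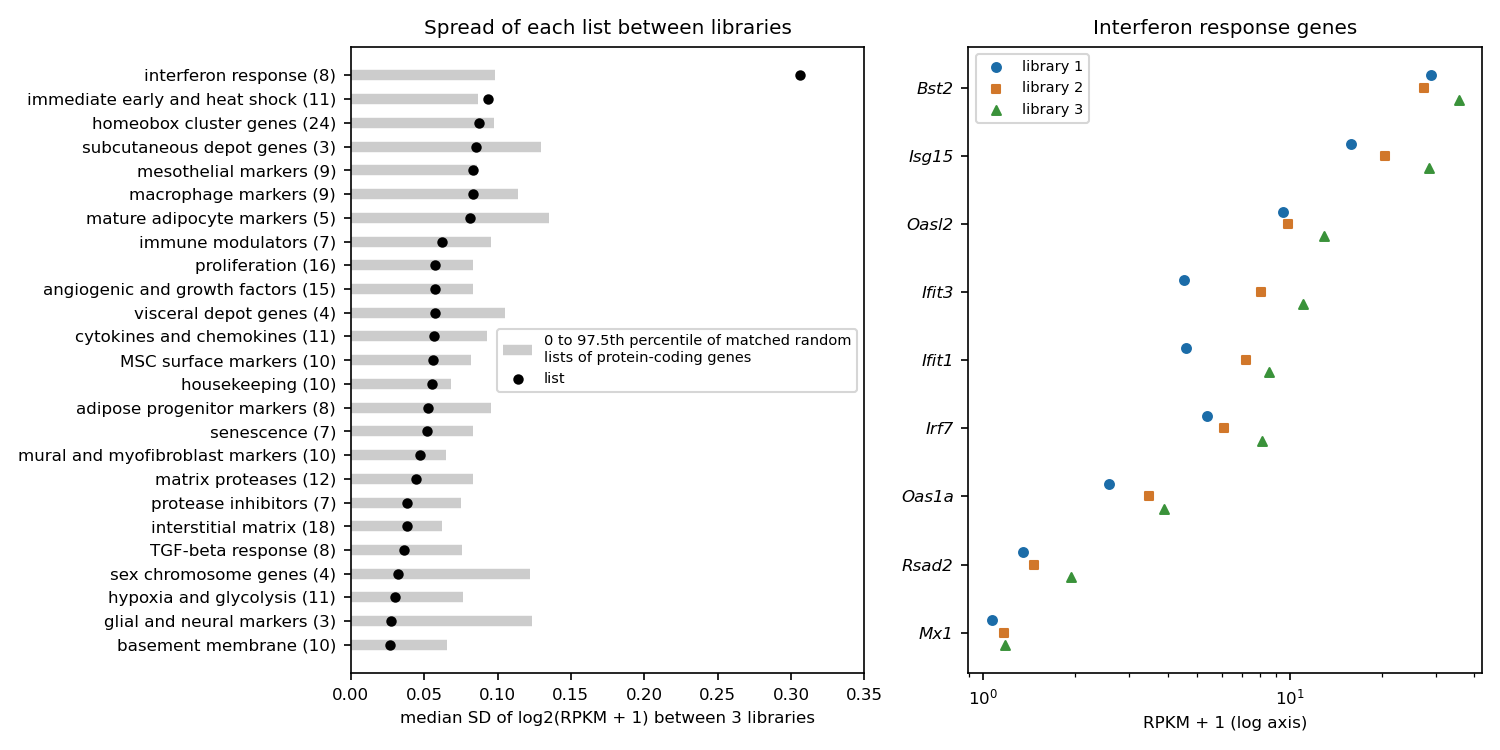
Left, the median SD of log2(RPKM + 1) between the 3 libraries for each list (points, number of members with a mean RPKM of 1 or more in brackets) and the range up to the 97.5th percentile of expression-matched random lists of protein-coding genes (bars). Right, the levels of 9 interferon response genes in each library, as RPKM + 1 on a logarithmic axis; the interferon list lies at 0.31 on the left, and library 3 is the highest of the 3 for all 9 genes on the right.

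Across the 10677 protein-coding genes with a mean RPKM of 1 or more, the median SD between libraries was 0.0607 on the log2(RPKM + 1) scale, and Pearson's r across genes was 0.996, 0.995 and 0.996 for libraries 1 and 2, 1 and 3, and 2 and 3. Genes are not independent replicates. 20 of these genes differed by more than 2-fold between the highest and the lowest library. Over all biotypes, 462 of 12974 genes did so, and 398 of them were annotated as small structural RNAs, that is, microRNA, small nuclear, small nucleolar, ribosomal or miscellaneous RNA genes. Without libraries 1, 2 and 3 in turn the count over all biotypes was 165, 242 and 305. The largest spread was that of the small nuclear RNA genes Gm23238, with 15.6, 0.735 and 97.0 in libraries 1, 2 and 3, Gm26244, with 21.5, 649 and 487, and Gm24830, with 16.6, 24.7 and 452. 209 genes lay more than 2-fold above or below both other libraries in a single library, most often above in library 1 with 73 genes, of which 69 were structural RNAs and 0 protein-coding. Of these 209 genes 8 were protein-coding, 4 of them above in library 3. Among them Gm10800 had 25.3, 46.5 and 122, Gm10801 4.88, 5.71 and 18.9 and Gm10282 2.49, 6.54 and 6.38 in libraries 1, 2 and 3.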

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

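No paired analysis was possible because the samples form a single group. The restrictions to protein-coding genes were chosen after the data were seen. Under the alternatives tried, the number of detected genes ranged from 8903 after rescaling to TPM to 13980 at a threshold of 0.5, and from 12460 to 12538 when 1 library was left out. Rescaling is dominated by the single feature Gm23935. The surface against haematopoietic contrast (range 3.07 to 6.05, adjusted exact permutation p at most 0.00530) and the mural against endothelial contrast (range 5.02 to 8.10, p at most 0.0134) kept their direction and call under all 7 alternatives. The progenitor against adipocyte difference was 0.97 with members below an RPKM of 0.1 left out, where fewer genes were tested, and 1.35 after rescaling, neither past the threshold. Rescaling lowered every value, the RPKM sums of libraries 1, 2 and 3 being 2.57e+06, 2.97e+06 and 2.99e+06, while the pseudocount stayed at 1. That by itself shrinks log2 differences, and whether it alone cost the call was not tested. With medians the visceral against subcutaneous difference was 2.38 and no longer past the threshold, and the osteogenic against chondrogenic difference reversed to -0.041; the cause was not tested. The contrasts between both matrix lists and between proteases and inhibitors stayed short of the threshold throughout. The count of genes differing by more than 2-fold was 750 with a pseudocount of 0.1, 219 at a mean RPKM of 5 or more, 20 among protein-coding genes, and 165 to 305 with 1 library left out, lowest without library 1, 242 without library 2 and highest without library 3. The count of genes apart in a single library was 773 at 1.5-fold, 446 with a pseudocount of 0.1, 85 at a mean RPKM of 5 or more and 8 among protein-coding genes. The number of lists above the 97.5th percentile ranged from 14 with genes below an RPKM of 0.1 left out to 19, and was 15 against protein-coding genes. The macrophage list left that range under 5 alternatives: percentile 48.5 with those genes left out, 97.36 after rescaling, 89.9 with means, 73.5 against protein-coding genes and 97.31 without library 2. With means the adipose progenitor and immune modulator lists entered that range, and the homeobox list left it. With genes below an RPKM of 0.1 left out, the cytokine list fell to 88.6, interferon response to 92.3, visceral depot to 96.24 and homeobox to 56.8. Against protein-coding genes the cytokine, interferon response and homeobox lists stood at 74.6, 96.16 and 79.1, also outside it. The cause of these shifts was not tested. Levels below about 0.104 RPKM are limited by depth.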

Other observations

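The tests of counting error, macrophage RNA, library scaling, a carried-over short-RNA fraction and sums with unrelated genes were chosen after the result was seen, as were the genes singled out below. A second list of interferon-induced genes followed the first. Of its 18 members with a mean RPKM of 1 or more, 18 were higher in library 3 than in library 1. In libraries 1, 2 and 3 the transmembrane protein transporter gene Rtp4 had 2.01, 2.52 and 3.93 RPKM, the nucleic acid sensor gene Zbp1 1.07, 1.36 and 2.13, Ifit2 3.40, 3.88 and 5.27, the RNA sensor gene Ifih1 1.91, 2.10 and 2.85 and the signalling gene Stat2 4.72, 5.06 and 6.03. The immunoproteasome gene Psmb8, with 3.59, 3.59 and 3.72, and Tap1, with 2.69, 2.51 and 2.89, differed less.

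The interferon response genes differed between libraries with a median log2(RPKM + 1) difference of 0.59 between libraries 3 and 1. The tables argue against counting error, since 8 of 8 genes had a 95% counting interval of the library 3 to library 1 ratio that excludes 1 even with the inferred reads halved. They argue against macrophage RNA as the whole cause, whose markers had a median difference of -0.0156 (standard error 0.0751) and whose most abundant marker, Lyz2, had 26.9, 24.5 and 27.2 RPKM in libraries 1, 2 and 3. Some leukocyte genes did differ in the same direction, namely Tyrobp of the macrophage list with 0.676, 1.83 and 2.99 RPKM, Itgam with 0.850, 1.03 and 1.36 and H2-Ab1 with 0.785, 0.926 and 1.14, while the pan-leukocyte gene Ptprc had 0.144, 0.133 and 0.131, and RNA of other leukocytes was not tested. The tables argue against library scaling, since protein-coding genes at a mean RPKM of 5 or more had a median difference of 0.000227. The second list had a median difference of 0.303, past the 0.3 set beforehand by less than its standard error of 0.0382. It was 0.08 between libraries 2 and 1 and 0.24 between libraries 3 and 2, both below 0.3, so the bound was passed only between libraries 1 and 3. A coordinated interferon-type response that differs between libraries 1 and 3 is a candidate explanation, as a hypothesis. Whether it reflects separate mice, culture dishes or handling stays open, because the labels give no such information, and no biological difference between the libraries was tested.

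Structural RNA genes made up 398 of the 462 genes that differed by more than 2-fold between libraries. Counting error was not tested for them. Whether their reads came from the annotated short RNAs, and how far the library protocol captures such RNAs, was not tested either. In a gene model of 1 kb, 1 read corresponds to an RPKM of 0.0347, 0.0303 and 0.0312 in libraries 1, 2 and 3. A shorter gene model reaches a given RPKM with fewer reads, so short genes near a mean RPKM of 1 rest on few reads. A candidate explanation is uneven assignment of reads among near-identical copies, and the tests leave it open. For the 11 genes with annotated copies among the most variable, the sum over the copies varied less than the gene itself, with a median ratio of SDs of 0.223. Those genes were picked for their spread, however, and a sum over many genes varies less in any case. Over all 394 structural RNA genes past 2-fold with a known length, 261 had no expressed copy. For the other 133 the median ratio was 0.616 with copies and 0.653 with as many unrelated genes of the same biotype. Sums with copies were the steadier for 65 genes, among them Gm23238 (ratio 0.0946 with copies, 0.228 with unrelated genes), Gm26244 (0.103 and 0.398) and Gm24830 (0.108 and 0.497), and sums with unrelated genes for 68. The direction differed between groups of copies, a split seen only afterwards. Small nuclear RNA genes with 23 to 37 expressed copies, those named included, were steadier with copies, except Gm24924 (0.248 and 0.225). All genes with 245 expressed copies, such as Gm23934 (0.693 and 0.548), were steadier with unrelated genes. The median difference per gene, the ratio with unrelated genes minus that with copies, was -0.00367 with a standard error of 0.00738, which decides neither way for the set. That error treats the genes as independent, though many share the same copies, so it may be too small. Class medians of the log2 difference between library 1 and the mean of the others were 0.98 for ribosomal, 0.56 for small nucleolar, 0.46 for small nuclear, 0.27 for miscellaneous and 0.18 for microRNA genes. The gap of 0.711 between ribosomal and miscellaneous RNA genes does not exclude a short-RNA fraction added to library 1, since such a fraction need not have the composition of the RNA already there, which was not measured. What sets the class differences stays open.

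All 37 genes of the mitochondrial chromosome, 13 of them protein-coding, were listed at 0 in every library. The nuclear-encoded respiratory chain genes had a median of 30.4 RPKM over 13 genes, with Cox4i1 at 72.6. This test was set up to exclude cells without mitochondrial transcription, but nuclear genes can stay transcribed without it, so the value does not decide. Absence of the mitochondrial genome from the alignment, reads aligned to it but not counted, and absent transcription cannot be told apart here. The highest of 15 nuclear copies, Gm10925 on chromosome 1 (24613974 to 24614651), identical to mt-Atp6, stood at a mean RPKM of 30.7, between the bounds of 10 and 100 set beforehand. Gm28661, identical to mt-Co2, had 19.9 and Gm28437, identical to mt-Co3, 15.9, while the median of the 15 copies was 1.32. A read within such an identical copy matches the mitochondrial gene equally well. The 0 at mt-Atp6, mt-Co2 and mt-Co3 therefore does not show that no matching read was sequenced. Whether the reads at the copies were nuclear or mitochondrial in origin was not tested.

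The feature with the highest RPKM was Gm23935, a gene of 57 bp annotated as a microRNA on chromosome 16 (11144125 to 11144181, mm10; sequence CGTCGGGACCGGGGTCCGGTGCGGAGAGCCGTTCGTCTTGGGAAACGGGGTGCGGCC), at 2069940, 2561280 and 2552790 in libraries 1, 2 and 3. By the inferred totals it took 11.8%, 14.6% and 14.6% of the reads. A ribosomal RNA precursor sequence was not used here, so whether these reads came from the annotated gene was not tested. Gm24270 and Gm24245, identical to it over all 57 bp, had mean RPKM values of 25941 and 9754.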
